A study of Nicotiana benthamiana and Cuscuta campestris and Nicotiana benthamiana
Cuscuta campestris with 12 samples.

How the data were processed

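Small RNA was sequenced from 12 libraries of a parasitic plant, the dodder *Cuscuta campestris*, grown on petioles of *Nicotiana benthamiana*, about 10 days after attachment per the labels. RNA was total RNA from a plant RNA kit, and libraries came from a low-bias small RNA kit with unique dual indexes. Groups were taken from the labels: haustorial interface, the site where the parasite feeds (n = 3), parasite shoot tips (n = 3), proximal petiole (n = 4) and distal petiole (n = 2). Libraries carry replicate names (PJF03 to PJF23) that no pair of groups shares, and nothing was paired. PJF03 to PJF06 and PJF07 to PJF10 each run in the order proximal petiole, shoot tips, interface, distal petiole. Libraries may thus have been collected in sets, which the labels do not state and no fit took into account. The labels also do not say whether replicates are separate plants. The p-values of group comparisons therefore measure the spread between libraries, and those of tests across features or miRNAs do not.

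The deposited values are RPM, reads per 1000000 of the library, as the authors made them; the column name points to reads of 21 to 24 nt, and the total of those reads is taken here as the library size. Every file lists the same 52471 features. They are 50362 loci of 24-nt siRNA, 1701 of 22-nt siRNA and 242 of 21-nt siRNA on 31 parasite chromosomes, 134 interface-induced miRNAs of the parasite and 32 canonical miRNAs. The median length of the siRNA loci is 427 nt. The aligner, the locus caller and the genome build are not given in the sources used here, nor is it stated whether a read can count both at an interface-induced miRNA and at a siRNA locus. Canonical miRNAs carry parasite names, but conserved sequences can come from either species. No feature is listed as belonging to the host alone, so the planned host comparisons, and the planned measure of host reads in shoot tips, could not be run; the canonical miRNAs were compared in their place, a choice made after the files were seen.

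Each value was a whole number of reads at a tolerance of 0.01 read, for 100% of values in every library, which gave back read counts and library totals. Totals ran from 2933082 reads (proximal petiole PJF23) to 20258153 reads (proximal petiole PJF07). A count of 3 reads was the floor and the detection minimum, equal to 0.148 RPM in PJF07 and 1.02 RPM in PJF23. Shares carry 95% exact Clopper-Pearson intervals. Intervals and floors cover counting error only, since reads made by PCR are not independent molecules. Every pair of replicates differed by more than sampling noise, with chi-square per degree of freedom from 3.62 to 29.3.

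Parasite features of interface and shoot tips were tested in the 6 libraries of both groups with limma 3.58.1 (trend) on log2 of the scaled value plus 1 RPM, in R 4.3.3. Scaling used TMM factors of edgeR 4.0.16 within parasite features, and filterByExpr left 46911 features. Proximal and distal petioles were compared over 26492 parasite features on RPM as deposited, and the 32 canonical miRNAs on RPM as deposited, with the petiole contrasts taken from a shared fit of the 9 libraries that hold host tissue. Calls are Benjamini-Hochberg adjusted p under 0.05. Class tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Group means of single values were compared with exact two-sided permutation tests (72 in the family) in scipy 1.17.1, with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15. For features called higher at the interface, detection in petioles was compared by Fisher's exact test across features with uncalled parasite features matched within 0.1 log2 of interface abundance (24 tests in the family).

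The choices of test, samples, alternatives, gene lists and naming rule were made before the data were examined. Named are up to 12 features per direction with the largest log2 fold change among those called, at 10 RPM or more in the higher group and with groups that do not overlap, miRNAs taken ahead of siRNA loci, and the 4 most abundant members of each list. The lists are developmental phase, auxin and tasiRNA, leaf and meristem, nutrient and copper, silencing machinery, immune receptor regulators, and parasite interface microRNAs (families ccm-miR12463, ccm-miR12480, ccm-miR12494, ccm-miR12495 and ccm-miR12497). No listed feature belongs to the immune receptor regulators, and no TAS3, chloroplast, mitochondrial, rRNA, tRNA or odd-sized features are listed. The most abundant called siRNA loci of each size class were named in addition, chosen after their values were seen.

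The tests were tried on simulated data, drawn from the means and dispersions of the compared libraries with known changes added. For interface and shoot tips, limma called 0% of added 2-fold changes, 19.4% of 4-fold and 59.7% of 8-fold, with 6 false calls. For proximal and distal petioles it called 3.4% of 8-fold changes and none of 4-fold, with 0 false calls. Among canonical miRNAs of interface and shoot tips, all 3 added 4-fold changes and all 5 added 8-fold changes were called. For petioles and canonical miRNAs, dispersions were taken relative to the reads at the simulated features, while counts were drawn from library totals. Spread between libraries in the share of these reads was thus not simulated. The parasite share ran from 0.17% to 22.1% in proximal petioles, so recovery in the real comparison can be lower. Alternatives were DESeq2 1.42.0 size factors, RPM without TMM, other filters and pseudocounts (0.1 and 5), the DESeq2 Wald test, other sets of libraries, a 2-fold minimum, leaving out each library in turn and, added after seeing the data, edgeR on the recovered reads, TMM in the RPM fits and fits without PJF07 and PJF23.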

Results

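Small RNAs were counted in 3 haustorial interface, 3 shoot tip, 4 proximal petiole and 2 distal petiole libraries. Interface libraries held 11808831 (PJF05), 11651569 (PJF09) and 13355698 (PJF13) reads of 21 to 24 nt, and shoot tips held 9553549 (PJF04), 11589495 (PJF08) and 14456390 (PJF12). Proximal petioles held 9057216 (PJF03), 20258153 (PJF07), 6996621 (PJF15) and 2933082 (PJF23), and distal petioles held 6750459 (PJF06) and 4844769 (PJF10). Interface tissue contains both species, shoot tips are parasite tissue away from the host, and petioles are host tissue on either side of the attachment.

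The parasite's small RNA make-up at the feeding site differed from that of its free shoots in the interface-induced miRNAs, a set in which some members are known to direct cleavage of host mRNAs. At the interface they made up 46279 ± 1810.3 RPM (SD, n = 3) against 75.9 ± 1.61 RPM in shoot tips (n = 3), a ratio of means of 609.7. As a share of all listed parasite reads this was 17.5% ± 1.18 against 0.024% ± 0.000794. The 24-nt siRNAs, the class known for directing DNA methylation, made up 73.0% ± 1.05 of parasite reads at the interface and 91.4% ± 0.255 in shoot tips. That total includes the interface-induced miRNAs, so their larger share at the interface lowers the 24-nt share by construction. The 21-nt siRNA loci held 1.54% ± 0.0426 against 1.08% ± 0.0411, and the 22-nt loci 7.98% ± 0.114 against 7.48% ± 0.266, while in RPM the 22-nt loci had the lower mean at the interface, with overlap between the groups, at 21276 ± 2470.7 against 23674 ± 1446 RPM. Each of these shares separated the 3 interface from the 3 shoot tip libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

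Listed parasite features took 26.6% ± 2.70 of interface reads and 31.6% ± 0.872 of shoot tip reads. The listed canonical miRNAs took another 1.45% and 0.702%, and the remainder fell on features not listed. Petiole libraries were far apart from each other. In proximal petioles the parasite share was 13.7% in PJF03, 22.1% in PJF07, 0.174% in PJF15 and 1.86% in PJF23, and in distal petioles 7.57% in PJF06 and 0.368% in PJF10. These shares count listed features only. They are to be read against the 31.6% of shoot tips, which are parasite tissue, so PJF07 and PJF03 need not be mostly host. Interface-induced miRNAs stood between the other groups, at 7250.3 ± 7906 RPM in proximal petioles (n = 4) and 6663 ± 8715 RPM in distal petioles (n = 2), with every petiole library above every shoot tip library and below every interface library. For these totals the exact permutation p was 0.0571 for the interface against proximal petioles and 0.2 against distal petioles, the smallest those group sizes allow, so no group comparison of this kind can pass 0.05. Proximal and distal petioles overlapped in parasite share, with an exact permutation p of 0.667.

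**Figure D1:**
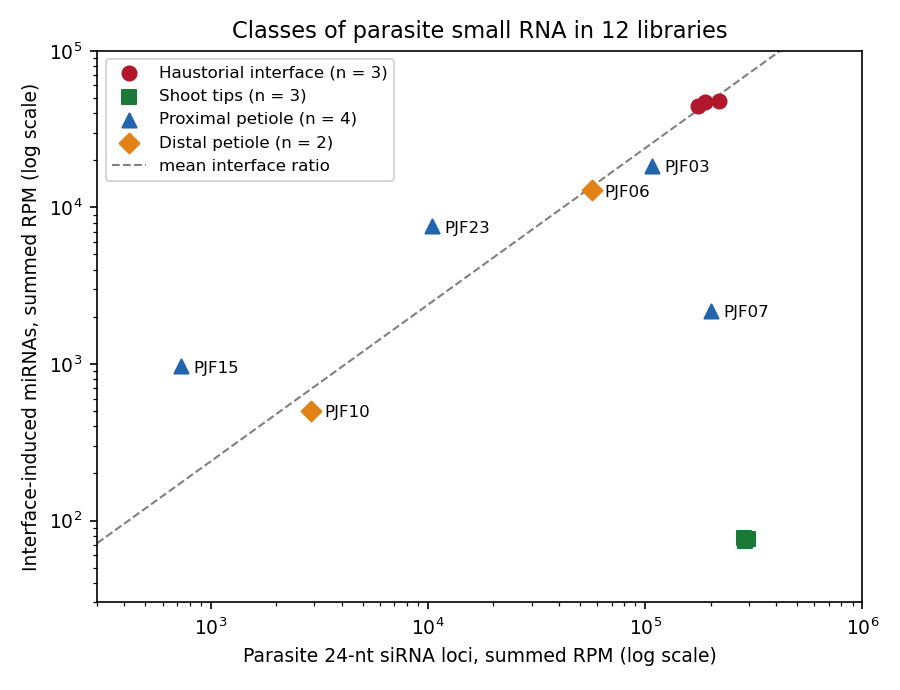
Summed RPM of interface-induced miRNAs (vertical) against summed RPM of parasite 24-nt siRNA loci (horizontal), both on log axes; each point is 1 of the 12 libraries, by group, and the dashed line is the mean ratio of the 3 interface libraries. Interface-induced miRNAs lie at 44217 to 47609 RPM at the interface, 74.1 to 77.2 RPM in shoot tips and 500.3 to 18307 RPM in petioles.

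Of the 131 interface-induced miRNAs tested between interface and shoot tips, 127 were higher at the interface and none lower, with a median log2 fold change of 8.42. The study defined this set by its induction at the interface, so the count is not independent evidence of the direction. ccm-miR12474b reached 1313.5 ± 88.3 RPM at the interface against 0.289 ± 0.266 RPM in shoot tips (log2 fold change 11.67, SE 0.301, adjusted p = 7.84e-09). ccm-miR12497f reached 2933 ± 419.9 RPM against 1.29 ± 0.701 RPM (log2 fold change 11.48, SE 0.310), and its pooled reads gave a ratio of 2183 with a counting interval of 1647 to 2961. ccm-IIM-12a, at 719.3 ± 155.6 RPM, and ccm-miR12490a, at 667.5 ± 76.9 RPM, each had 2 reads over all shoot tip libraries. Their pooled ratios were 12941 (3582 to 106861) and 11815 (3270.4 to 97567). ccm-IIM-56, ccm-miR12474a, ccm-IIM-94, ccm-IIM-76a, ccm-miR12485, ccm-IIM-109, ccm-IIM-34a and ccm-miR12466b complete the named set, with log2 fold changes from 11.56 down to 10.48. The most abundant members, chosen after their values were seen, were ccm-miR12487b at 3733 ± 837.5 RPM and ccm-miR12492a at 3042 ± 672.2 RPM, against 6.19 ± 0.930 and 3.66 ± 1.09 RPM in shoot tips.

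The families fixed as parasite interface microRNAs were higher as well. All 15 tested members were higher, with a median log2 fold change of 8.23, and 15 were also called when adjusted over the list alone. ccm-miR12494b stood at 782.0 ± 145.1 RPM against 0.825 ± 0.173 RPM, ccm-miR12480b at 758.9 ± 50.01 RPM against 0.873 ± 0.549 RPM, and ccm-miR12495ac at 652.0 ± 119.8 RPM against 3.58 ± 1.10 RPM (n = 3 in each group). This list overlaps the study's own set and is no independent evidence either. Over all interface-induced miRNAs, 131 of 131 were called when adjusted over the list alone, and all 131 had every interface library above every shoot tip library, where chance gives 10% for 3 against 3 in either order. Of the tested members, 25 had 0 reads over the shoot tip libraries and 22 had 1 to 3; with shoot tip reads under 3 set to 3, the median pooled ratio was 462.5-fold and the lowest 7.03-fold. Tested but not called were ccm-IIM-104a, ccm-IIM-63b, ccm-IIM-9 and ccm-miR12490c, which had 92, 60, 65 and 298 reads over the interface libraries. ccm-IIM-104b, ccm-IIM-84 and ccm-miR12490b fell under the filter, the last with 0 reads in both groups; these 7 were named after their values were seen. In camera the set was higher (adjusted p = 5.31e-315, and adjusted p = 0.000219 with an estimated correlation), as was the list of families (adjusted p = 2.92e-76, and adjusted p = 0.000851 with an estimated correlation).

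Parasite siRNA loci were called far less often, and those called higher at the interface were concentrated among the 21-nt and 22-nt loci, though not in a fit of all 12 libraries, which called none of these. Of the 138 tested 21-nt loci 11 were higher and none lower, of 1182 22-nt loci 30 were higher and 3 lower, and of 45460 24-nt loci 25 were higher and 13 lower. The odds of a higher call among siRNA loci were 73.4 times those of other classes for 21-nt loci (Fisher's exact test across features, p = 9.17e-17) and 33.0 times for 22-nt loci (p = 1.92e-30). Among 22-nt loci the odds of a lower call were raised too, at 8.92 times those of other classes, though on only 3 loci. The odds were not matched on abundance, so by themselves they do not show a rise specific to a size class. Adjusted over the list alone, 27 of the 21-nt loci were higher and 3 lower, 48 of the 22-nt loci higher and 14 lower, and 2 of the 24-nt loci higher and none lower. The 21-nt class was higher in camera (median log2 fold change 0.47, turning to -0.08 on RPM as deposited, adjusted p = 6.07e-09, and adjusted p = 0.00102 with an estimated correlation). The 24-nt class came out lower in camera (adjusted p = 1.33e-06, and adjusted p = 0.000219 with an estimated correlation) at a median log2 fold change of only -0.02. The 22-nt class did not pass (adjusted p = 0.744). Camera ranks a class against all other features. For the 24-nt loci these include the 131 interface-induced miRNAs, at a mean log2 fold change of 8.09, so camera does not show a fall of this class. In fry, which tests a class on its own, the directional p was 0.175. The loci named next were the most abundant called ones of each size class, and Cluster_49940 for its position, all chosen after their values were seen.

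The 22-nt locus Cluster_49941 (chromosome 21, 9398870 to 9401272, build not given in the sources used here) rose from 94.1 ± 19.2 RPM in shoot tips to 1005.5 ± 156.1 RPM at the interface (log2 fold change 4.0, SE 0.172, adjusted p = 3.63e-07). Beside it, Cluster_49940 (chromosome 21, 9397986 to 9398534) rose from 4.53 ± 2.33 to 56.2 ± 8.96 RPM (log2 fold change 4.21), and Cluster_49936 (chromosome 21, 9389226 to 9391797) from 911.5 ± 72.5 to 1219 ± 171.7 RPM (log2 fold change 1.0). The 24-nt loci between them, Cluster_49937 and Cluster_49939, were not called, with log2 fold changes of -0.81 and 0.28. Of the other abundant 22-nt loci, Cluster_26745 (chromosome 10) stood at 830.2 ± 170.0 against 555.6 ± 20.0 RPM (log2 fold change 1.145) and Cluster_64648 (chromosome 29) at 780.7 ± 212.5 against 429.2 ± 41.0 RPM (log2 fold change 1.416). Among 21-nt loci, Cluster_23950 (chromosome 10, 193116 to 193834) stood at 836.0 ± 121.6 RPM against 192.7 ± 114.7 RPM (log2 fold change 2.96, adjusted p = 0.0213), Cluster_33286 (chromosome 13) at 680.4 ± 105.3 against 549.4 ± 18.1 RPM (log2 fold change 0.882), Cluster_24584 (chromosome 10) at 196.9 ± 50.2 against 83.2 ± 4.72 RPM, and Cluster_3964 (chromosome 2) at 152.7 ± 20.6 against 77.1 ± 5.25 RPM. Among 24-nt loci, Cluster_37637 (chromosome 15, 15547652 to 15548276) stood at 66.6 ± 30.9 RPM against 4.24 ± 1.83 RPM (log2 fold change 4.38) and Cluster_23044 (chromosome 9, 12840783 to 12841213) at 38.0 ± 4.81 against 5.57 ± 2.40 RPM (log2 fold change 3.34), with Cluster_31412 and Cluster_36714 at log2 fold changes of 2.096 and 0.997. Cluster_23950 lost its call without PJF05, PJF09 or PJF13, and Cluster_49936 lost its call without PJF08 and on RPM as deposited (log2 fold change 0.41). Cluster_33286, Cluster_26745, Cluster_64648, Cluster_31412 and Cluster_36714 were not called on RPM as deposited either, and Cluster_33286, Cluster_31412 and Cluster_36714 also lost their calls with edgeR and when single libraries were left out.

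**Figure D2:**
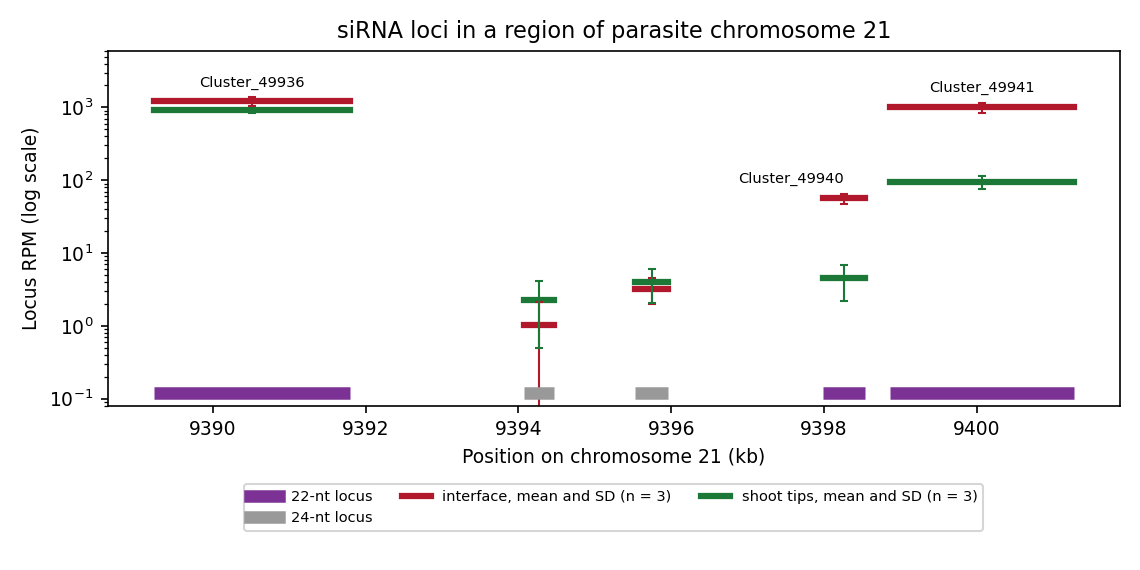
Parasite siRNA loci on chromosome 21 by position; horizontal lines over each locus are mean RPM (log axis) at the interface and in shoot tips, 3 libraries each, error bars are SD and run below the axis where SD exceeds the mean, and bars at the bottom mark the loci by size class. Cluster_49941 and Cluster_49940 stand at 1005.5 and 56.2 RPM at the interface against 94.1 and 4.53 RPM in shoot tips.

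The loci lower at the interface were less abundant. Among the 24-nt loci, Cluster_42359 (chromosome 18, 1887058 to 1887624) stood at 0.285 ± 0.358 RPM at the interface against 10.7 ± 1.33 RPM in shoot tips (log2 fold change -4.06, SE 0.573, adjusted p = 0.0102). Cluster_67538, Cluster_37022, Cluster_10041, Cluster_33304, Cluster_64430 and Cluster_29421 had log2 fold changes of -3.48, -2.57, -2.39, -1.63, -1.53 and -1.42. The 22-nt loci that were lower were Cluster_55912 (chromosome 24), at 56.2 ± 8.15 against 155.8 ± 14.3 RPM, Cluster_51959 (chromosome 22), at 18.7 ± 2.92 against 65.5 ± 7.58 RPM, and Cluster_66747 (chromosome 30), at 14.0 ± 3.53 against 49.0 ± 6.93 RPM. All 3 interface libraries lay below all 3 shoot tip libraries at each named locus, as the naming rule requires.

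In total limma called 193 parasite features higher and 16 lower of 46911, and 5014 had an unadjusted p under 0.05. These changes are relative to TMM scaling within parasite features, since on RPM as deposited the median log2 fold change of all features moved from -0.02 to -0.46 and that of 21-nt loci from 0.47 to -0.08. On that scale the share of calls that were higher went from 92.3% to 21.9%, with 35 siRNA loci higher and 579 lower, against 66 and 16 with TMM, and the 22-nt loci turned to 14 higher and 45 lower and the 24-nt loci to 13 higher and 531 lower. DESeq2's Wald test called 352 siRNA loci higher and 266 lower (284 and 244 of them 24-nt loci), and a fit of all 12 libraries called 3 and 2, all of them 24-nt loci. The lower siRNA loci numbered 0 without PJF08, 1 without PJF04, 8 without PJF09 and 8 without PJF12, and the higher ones 32 without PJF05 and 40 without PJF09.

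**Figure D3:**
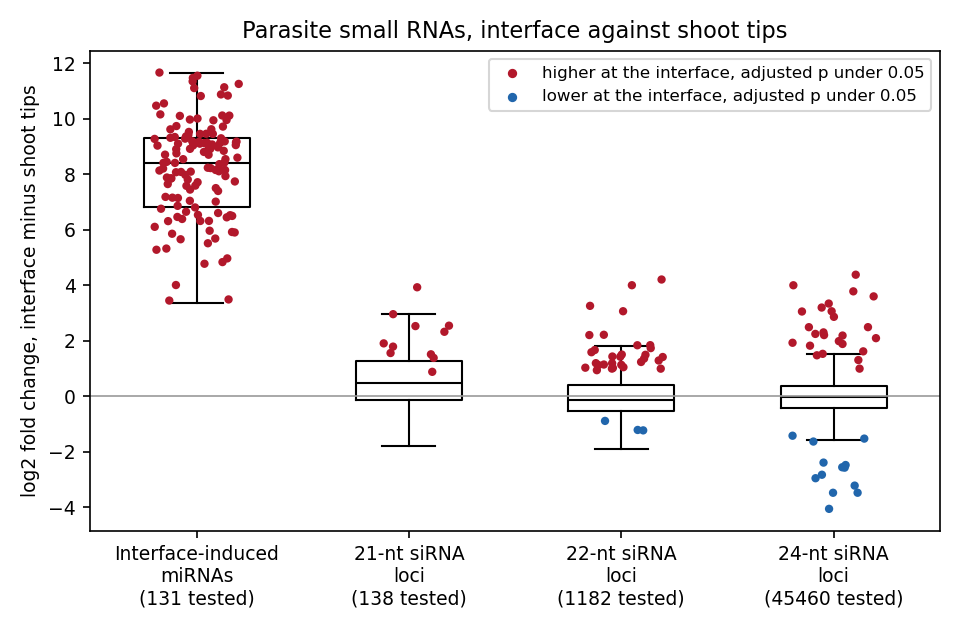
Log2 fold change of tested parasite features, interface minus shoot tips (limma, 3 against 3 libraries), by class; boxes show the quartiles and median of all tested features, with outlying values not drawn, and points are the called features, higher or lower. The 131 interface-induced miRNAs have a median of 8.42, and the 24-nt loci a median of -0.02.

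Canonical miRNAs, counted from both species at the interface, were compared between interface and shoot tips after the files were seen. Interface libraries hold host tissue and shoot tips do not, so a higher call can come from host miRNAs alone. Of the 32 listed, 12 were higher at the interface and none lower, among them 3 of the 4 listed members of the miR169 family, regulators of NF-Y transcription factors. ccm-miR169d and ccm-miR169f had the largest log2 fold changes, while ccm-miR169c, at 4.88, stood below ccm-miR164c and ccm-miR396abcd. ccm-miR169d rose from 0.497 ± 0.0698 to 352.6 ± 67.5 RPM (log2 fold change 7.87, SE 0.277, adjusted p = 2.69e-07), and ccm-miR169f from 0.334 ± 0.225 to 246.1 ± 21.2 RPM (log2 fold change 7.54). ccm-miR169c, at 28.5 ± 3.41 RPM, had 0 reads in the shoot tip libraries and was at least 337-fold higher against a floor of 3 reads over the group. The other member, ccm-miR169e, went the other way without a call, at 2.10 ± 1.64 against 5.20 ± 3.89 RPM (log2 fold change -0.826, adjusted p = 0.377). With these members, 3 of 6 on the nutrient and copper list were higher. The copper miRNAs of that list did not pass in limma but did in edgeR (adjusted p = 0.0322 for ccm-miR408ab and adjusted p = 0.0259 for ccm-miR398ab) and in DESeq2, with 159.8 ± 193.4 against 25.3 ± 6.53 RPM for ccm-miR408ab (adjusted p = 0.132) and 45.3 ± 53.4 against 6.37 ± 1.63 RPM for ccm-miR398ab (adjusted p = 0.0907). Both had their highest interface value in PJF13, at 382.4 and 106.8 RPM.

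On the leaf and meristem list 4 of 14 members were higher. They were ccm-miR164c, a regulator of NAC transcription factors, at 692.2 ± 81.9 against 14.2 ± 5.07 RPM (log2 fold change 5.55), ccm-miR164abde (log2 fold change 4.57), ccm-miR171d (log2 fold change 1.795) and ccm-miR396abcd, a regulator of growth-regulating factors, at 3272 ± 805.3 against 99.7 ± 51.7 RPM (log2 fold change 5.15). The other abundant members were not called, with log2 fold changes of 0.349 for ccm-miR159ab and 0.425 for ccm-miR166ai, both below 0 with size factors or TMM, and -0.434 for ccm-miR166bcdf. On the developmental phase list 3 of 6 were higher. They were ccm-miR156dgijkl, a regulator of SPL transcription factors, at 1928 ± 492.4 against 98.5 ± 71.6 RPM (log2 fold change 4.47), ccm-miR156h (log2 fold change 2.62) and ccm-miR172bc (log2 fold change 1.66, adjusted p = 0.0499). Other members of these families were not called, with log2 fold changes of 0.023 for ccm-miR156b (below 0 with size factors or TMM), -1.08 for ccm-miR156m and -1.20 for ccm-miR172ad. On the auxin and tasiRNA list 1 of 3 was higher, ccm-miR390ab, which triggers tasiRNA formation, at 202.9 ± 60.2 against 33.4 ± 23.5 RPM. ccm-miR160abcd and ccm-miR167ab had log2 fold changes of -0.495 and 0.298, the latter below 0 with size factors or TMM. On the silencing machinery list 1 of 3 was higher, ccm-miR168cd, a regulator of ARGONAUTE mRNA, at 471.9 ± 95.2 against 173.2 ± 61.6 RPM (log2 fold change 1.49). Counts adjusted over the list alone were the same for each list.

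In limma 14 of the 32 had an unadjusted p under 0.05, and no list passed in camera, with the smallest adjusted p at 0.236 for nutrient and copper (adjusted p = 0.511 with an estimated correlation). The developmental phase, auxin, leaf and silencing lists had positive medians and a camera direction below the other miRNAs. The lower side depended on scaling. The median log2 fold change of the 32 moved from 0.41 on RPM to -0.40 with DESeq2 size factors and -0.27 with TMM, where 8 and 6 miRNAs were lower, among them ccm-miR172ad, ccm-miR160abcd and ccm-miR166bcdf, and 9 and 10 higher, with ccm-miR390ab and ccm-miR172bc not called in either and ccm-miR168cd not called with size factors. A fit of all 12 libraries called 8 in place of 12, without ccm-miR171d, ccm-miR168cd, ccm-miR172bc and ccm-miR390ab, and ccm-miR172bc was not called with edgeR or a pseudocount of 0.1. Leaving out a library ended the call of ccm-miR168cd (PJF05, PJF09 or PJF13), ccm-miR172bc (PJF04, PJF09, PJF12 or PJF13) and ccm-miR390ab (PJF09 or PJF13), and made calls of ccm-miR398ab and ccm-miR408ab (PJF05, log2 fold changes 2.65 and 2.62). It also made lower calls of ccm-miR156m (without PJF08, log2 fold change -1.82) and of ccm-miR169e and ccm-miR172ad (without PJF12, log2 fold changes -1.56 and -1.74).

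**Figure D4:**
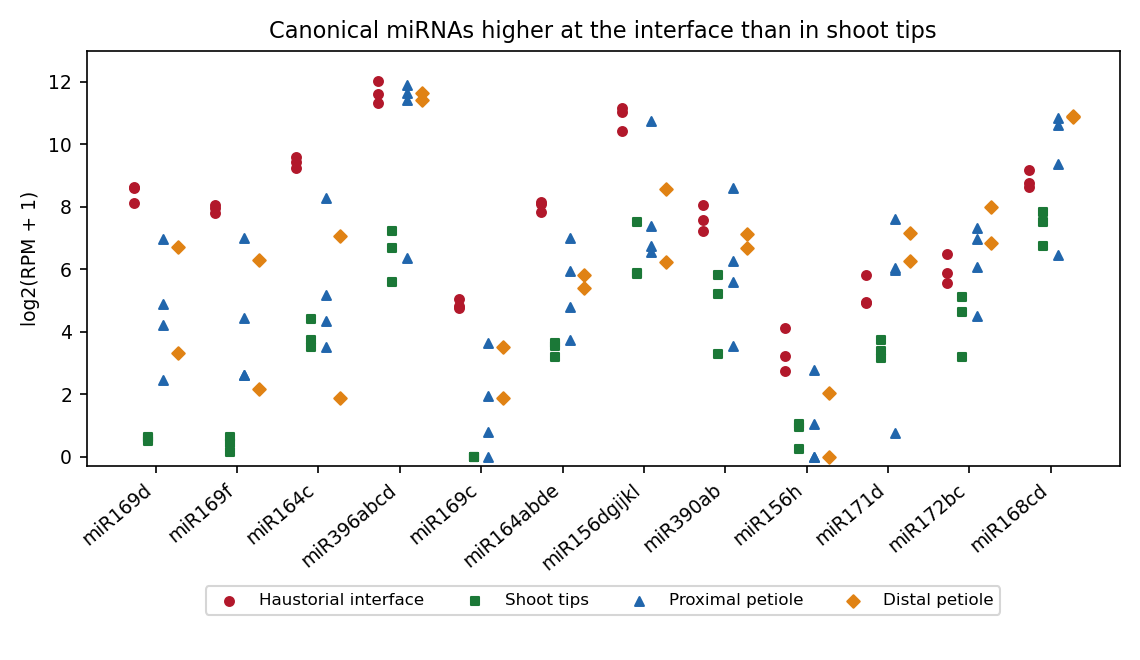
Log2 of RPM plus 1 of the 12 canonical miRNAs called higher at the interface than in shoot tips, in order of log2 fold change; each point is a library, by group, all 12 libraries shown. ccm-miR169d lies at 274.9 to 396.0 RPM at the interface and at 0.419 to 0.553 RPM in shoot tips, while ccm-miR168cd lies at 1565 to 1925 RPM in 4 of the 6 petiole libraries.

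Against the petioles the same miRNAs had fold changes of both signs and a wide spread. ccm-miR169d stood at 352.6 ± 67.5 RPM at the interface against 43.4 ± 54.1 RPM in proximal petioles (n = 4) and 56.7 ± 67.6 RPM in distal petioles (n = 2). ccm-miR156dgijkl stood at 525.2 ± 807.7 and 227.5 ± 216.7 RPM in proximal and distal petioles, against 1928 ± 492.4 RPM at the interface. ccm-miR396abcd was abundant in petioles, at 2462 ± 1649 RPM in proximal and 2951 ± 313.0 RPM in distal petioles against 3272 ± 805.3 RPM at the interface. ccm-miR168cd stood at 1038 ± 809 RPM in proximal and 1901 ± 33.9 RPM in distal petioles, above the 471.9 ± 95.2 RPM of the interface in group means. ccm-miR171d and ccm-miR172bc were also higher in distal petioles in group means, at 109.4 ± 47.6 and 181.9 ± 98.0 RPM against 37.96 ± 14.8 and 63.86 ± 22.1 RPM at the interface (log2 fold changes -1.495 and -1.437), and stood at 0.132 and -0.245 against proximal petioles. PJF23 stood apart from the other petioles for canonical miRNAs, with 545.2 RPM in all against 10389 to 18013 RPM. PJF15 and PJF10, with the lowest parasite shares, held 3205 and 2729 RPM of ccm-miR396abcd and 1837 and 1877 RPM of ccm-miR168cd. Of ccm-miR171d they held 192.8 and 143.0 RPM, and of ccm-miR172bc 157.2 and 251.2 RPM. For these, host tissue at the interface cannot be told apart from a rise in the parasite. The other called miRNAs stood below every interface library there, ccm-miR169d at 4.43 and 8.88 RPM. In PJF03, however, ccm-miR390ab stood above every interface library, at 384.2 RPM. There ccm-miR156dgijkl and ccm-miR156h lay within the interface range, at 1736 and 5.85 RPM, and the rest of these miRNAs below it. Low levels in PJF15 and PJF10 do not show which species these miRNAs came from at the interface.

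None of the 32 canonical miRNAs passed in limma for the interface against proximal petioles, where the smallest adjusted p was 0.0962 and 10 had an unadjusted p under 0.05. The counts were 0 also in edgeR (2 with an unadjusted p under 0.05) and in DESeq2 (3 with an unadjusted p under 0.05). Against distal petioles the limma count was 0 (smallest adjusted p 0.087, 5 with an unadjusted p under 0.05), as in edgeR (2) and DESeq2 (6). Adjusted over the list alone, 1 member each of the developmental phase, leaf and meristem and silencing machinery lists was higher than in proximal petioles, 2 of the leaf and meristem list were higher than in distal petioles, and 0 of the auxin and nutrient lists passed in either. The calls turned on single choices. Without PJF03, 7 were higher than in proximal petioles (ccm-miR156b, ccm-miR156dgijkl, ccm-miR156h, ccm-miR164c, ccm-miR169c, ccm-miR169d and ccm-miR169f), without PJF07 1 was (ccm-miR171c), and without PJF06 1 was higher than in distal petioles (ccm-miR164c). With only the 2 groups in the fit, 16 were higher than in distal petioles and 1 lower. Without PJF07 and PJF23, ccm-miR168cd was lower at the interface than in proximal petioles (log2 fold change -1.86, adjusted p = 0.0115) and than in distal petioles (log2 fold change -2.03, adjusted p = 0.00646). Over all alternatives its adjusted p ran from 0.00485 to 1.0 against proximal and from 0.000414 to 0.871 against distal petioles.

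Reads of small RNAs called higher at the interface were also found in petiole libraries, where small RNAs inside host tissue and carried-over parasite tissue were not separated by a test. Of the 127 interface-induced miRNAs called higher at the interface, proximal petioles held at least 3 reads of 126 in PJF03, 119 in PJF07, 93 in PJF15 and 110 in PJF23, and distal petioles of 123 in PJF06 and 60 in PJF10. These are 99.2%, 93.7%, 73.2% (exact interval 64.7% to 80.7%), 86.6% (79.4% to 92.0%), 96.9% and 47.2% (38.3% to 56.3%). In all 4 proximal libraries 90 of the 127 were found, in both distal libraries 60, in all 6 petiole libraries 58, and 1 in none. Shoot tips, where the set is low, still held 58 to 66 of the 134 listed miRNAs at 3 reads or more. Of the 66 siRNA loci called higher, 60, 65, 12 and 41 were found in PJF03, PJF07, PJF15 and PJF23, and 59 and 20 in PJF06 and PJF10. Abundant members were found at high mean levels: ccm-miR12497f stood at 459.4 ± 548.3 RPM in proximal and 647.7 ± 889.1 RPM in distal petioles, and ccm-miR12487b at 561.1 ± 628.6 and 626.6 ± 799.1 RPM. Single libraries carried these means. For ccm-miR12497f, PJF03 had 1271 RPM against 98.6 to 310.3 in the other proximal petioles, and PJF06 had 1276 against 19.0 in PJF10.

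Detection of 66 of the miRNAs was compared with that of a matched uncalled feature each (median 51.8 against 52.0 RPM at the interface). The uncalled features were siRNA loci apart from 4 miRNAs, so miRNAs were set against siRNA loci. The outcome thus follows the interface-induced miRNA reads per 24-nt siRNA read of a library, 1.32 in PJF15, 0.723 in PJF23 and 0.0109 in PJF07. It is no separate evidence of detection beyond abundance. In PJF15, 54.5% of the miRNAs were found against 13.6% of their matches (Fisher's exact test across features, adjusted p = 2.52e-05), and in PJF23 75.8% against 51.5% (adjusted p = 0.017). In PJF07 the order turned, with 87.9% of the miRNAs against 100% of the matches (adjusted p = 0.017). PJF03, PJF06 and PJF10 did not pass, with 98.5% against 100%, 93.9% against 98.5% and 25.8% against 36.4%. Features are not independent replicates, and the most abundant miRNAs had no match, the highest matched one being at 480.4 RPM.

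No parasite feature was called different between proximal and distal petioles. Spread in the listed families was as large as the means, with ccm-miR12480b at 167.0 ± 207.7 RPM in proximal (n = 4) against 101.6 ± 121.5 RPM in distal petioles (n = 2), ccm-miR12495ac at 144.8 ± 192.8 against 82.1 ± 110.0 RPM, and ccm-miR12494b at 121.4 ± 143.9 against 111.8 ± 154.9 RPM. Of 26492 features tested in limma 0 were called and 0 had an unadjusted p under 0.05; edgeR called 0 (0 with an unadjusted p under 0.05) and DESeq2 called 0 (152 with an unadjusted p under 0.05). None of the 14 parasite interface microRNAs tested passed, nor did any when adjusted over the list alone. Camera placed the interface-induced miRNAs below other parasite features (adjusted p = 1.72e-05, with their median log2 fold change at 0.53 and that of all features at 0.55, which ranged from -0.107 without PJF07 to 0.96 without PJF15), a call lost at adjusted p = 0.965 with an estimated correlation. Canonical miRNAs gave 0 of 32 calls and 0 with an unadjusted p under 0.05 in limma, 0 in edgeR and 0 in DESeq2 (1 with an unadjusted p under 0.05 in each). With spread this wide, 8-fold changes would rarely be seen, and the comparison does not show that both sides are alike.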

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

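The 5 values below were set apart by the gap between a library and the nearest of the other 3 proximal petiole libraries; of 34 measures tried 5 passed, where chance alone gives about 1 in 20. The tests of interface tissue, of shoot tips as the only source and of a wrong label in PJF07 were chosen only after its values were seen, and the test for shoot tissue was written before.

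In PJF03, ccm-miR156dgijkl stood at 1736 RPM, against 92.7 to 167.0 RPM in the other proximal petioles, and ccm-miR169f at 127.0 RPM, against 5.11 to 20.8 RPM. In PJF07, ccm-miR172ad stood at 118.4 RPM against 0 to 11.2 RPM, ccm-miR167ab at 118.1 RPM against 0.682 to 16.3 RPM, and ccm-miR168b at 0.790 RPM against 0 reads in the others. The last value rests on few reads, and the 0 reads of the others put its ratio at 1.0 whatever its size.

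PJF07 also held the highest listed parasite share of the petiole libraries, 22.1%, where shoot tips had 31.0% to 32.6%. It held 200424 RPM of 24-nt siRNA but only 2181 RPM of interface-induced miRNAs. Interface tissue alone, shoot tip tissue alone, and a library of either kind under the wrong label are argued against by 0.0109 interface-induced miRNA reads per 24-nt siRNA read (counting interval 0.0108 to 0.0110), where interface libraries had 0.217 to 0.252 and shoot tips 0.000257 to 0.000273. Shoot-like tissue may have entered this library beside another source: siRNA loci lower at the interface had 0.0804 reads per read at loci higher there (0.0783 to 0.0825), where shoot tips had 0.0678 to 0.0772 and the interface 0.00966 to 0.010. That value lies slightly beyond the shoot tip range, and other parasite tissue of like make-up was not sampled. A swap with another petiole or an outside library and a biological route into the petiole were not tested and stay open.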

How the results depend on the processing

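Alternatives with edgeR, with TMM in the RPM fits, without PJF07 and PJF23, and every alternative for canonical miRNAs were chosen after seeing the data. The 127 higher interface-induced miRNAs numbered 122 to 131 in every setting run with all libraries kept and 124 to 125 with a library left out, and no called parasite feature changed sign in any setting. Calls among all parasite features went from 209 to 741 on RPM as deposited (siRNA loci 35 higher and 579 lower), to 749 with the DESeq2 Wald test (352 and 266) and to 127 with all 12 libraries in the fit (3 and 2), a fit that shares its spread with the petioles. Lower siRNA loci went from 16 to 8 with edgeR and to 8 with a pseudocount of 0.1. With a library left out, siRNA loci ranged from 32 to 80 higher and from 0 to 14 lower. Canonical miRNAs lower at the interface than in shoot tips went from 0 to 8 with DESeq2 size factors, 6 with TMM and 1 with the DESeq2 Wald test, and from 0 to 2 with a library left out. Against proximal petioles, higher calls went from 0 to 3 with a pseudocount of 5 and ranged from 0 to 7 with a library left out, and lower calls went to 1 with DESeq2 size factors, with TMM and without PJF07 and PJF23. Against distal petioles, higher calls went from 0 to 16 with only the 2 groups compared and to 3 with a pseudocount of 5, and ranged from 0 to 1 with a library left out; lower calls went to 1 with DESeq2 size factors, 2 with TMM, 1 with only the 2 groups and 1 without PJF07 and PJF23. Beyond the RPM scaling, which lowered the median of all features and of 21-nt loci, the cause was not tested.

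Without the 10 most abundant parasite features, interface-induced miRNAs took 12.5% of parasite reads at the interface, 0.0178% in shoot tips and 9.72% in distal petioles. The 21-nt loci took 1.38% and 0.915% at the interface and in shoot tips, the 22-nt loci 7.74% and 7.06%, and the 24-nt loci 78.4% and 92.0%, with 82.9% in distal petioles; part of the reads is removed by construction. Values of this kind moved in 45 alternatives, those given here, and stayed within the set margin in 252. Single named features kept their side of the threshold in 1644, with 34 gaining and 138 losing a call; among those that were not called, the sign differed in 131 cases. Counts for the make-up of the interface-induced miRNAs moved in 8. Planned comparisons of host features, host reads in shoot tips, and a size filter that every feature passes were not run, and total reads without TMM is already the scaling used for the petioles. Where a group was left with 1 library, that library was assumed to vary like the others. Depth limits PJF23, PJF10 and PJF06 most, where 3 reads stand for 1.02, 0.619 and 0.444 RPM.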

Other observations

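The loci called higher among siRNAs were counted by position, and the make-up of the interface-induced miRNAs in petioles was compared with that at the interface, both chosen after the data were seen. So were the tests of carry-over, read transfer and host small RNAs given here and the splits of the interface comparisons. The tests of GC content, length, abundance and splits for the make-up were written before their results, and the intervals of rho that they are held to were added after.

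The siRNA loci called higher at the interface stood close together more often than matched loci. Of 66 higher loci, 9 had another higher locus within 10 kb, where 10000 draws matched on class and abundance gave a mean of 3.40 and at most 15 (one-sided permutation p = 0.0200). They were the 22-nt loci Cluster_49936, Cluster_49940 and Cluster_49941 on chromosome 21 and pairs on chromosomes 10, 13 and 20. Some nearly touch: Cluster_26744 ends at 16356238 and Cluster_26745 starts at 16356376, and Cluster_47273 ends at 3824855 and Cluster_47274 starts at 3824951. Such pairs may be 1 source listed as separate loci, which the draws do not allow for. Cluster_26745 and Cluster_49936 were not called on RPM as deposited, and the count was not repeated on that scale. None of the 16 lower loci had such a neighbour (mean of draws 0.0340, permutation p = 1).

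Within the class, some shares in petioles differed from those at the interface, though ranks were largely kept. Spearman rho across miRNAs with the interface mean ran from 0.758 in PJF10 to 0.961 in PJF06. PJF10 and PJF15 had only 2423 and 6739 reads at the miRNAs compared, against 545072 or more in each interface library. Of 110 interface-induced miRNAs with at least 20 RPM at the interface, 33 held a lower share of the class in the 6 petiole libraries and 1 a higher share, by limma-voom. The median log2 fold change of the 110 was -0.745. The direction of these calls is thus relative to the summed reads of the class, which abundant members weigh on most. Scaling to the median miRNA was not tried. ccm-IIM-87 took 0.142% ± 0.101 of the class at the interface (n = 3) and 1.21% ± 0.934 in petioles (n = 6), a log2 fold change of 3.10 (SE 0.659, adjusted p = 0.00789), above the interface mean in 6 of 6 petioles. ccm-miR12474b took 2.84% ± 0.0821 and 1.15% ± 0.856, and ccm-miR12469bc 1.03% ± 0.207 and 0.270% ± 0.292. The lower count fell to 12, 14, 9 and 9 without PJF05, PJF09, PJF13 and PJF15, and to 8 without PJF10 and PJF15, while the higher count was 3 without PJF06, 4 without PJF23 and 3 without PJF07 and PJF23.

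An arbitrary split of the libraries is argued against, since of the 84 splits of the 9 libraries only the real 1 gave as many calls (34, with 5 the highest of the others). Length stays open, with a Spearman rho of 0.156 across miRNAs between length and log2 fold change (95% interval -0.033 to 0.335, two-sided permutation p = 0.103, adjusted p = 0.103) and a median log2 fold change of -1.235 for the 48 miRNAs of 21 nt against -0.578 for the 56 of 22 nt. GC content may account for part of it: rho was 0.511 across the 110 miRNAs (95% interval 0.348 to 0.645, Pearson r 0.526, permutation p = 1e-05, the smallest 100000 draws give, adjusted p = 3e-05). The interval reaches below the bound set beforehand, which rho itself passes only narrowly. The 48 miRNAs of GC below the median had a median log2 fold change of -1.35 against -0.31 in the other 62. Abundance at the interface stays open at rho 0.355 (Pearson r 0.275, permutation p = 0.00014, adjusted p = 0.00021), between the bounds set for it. miRNAs are not independent replicates, rho with GC was -0.006 in PJF23 and 0.364 to 0.567 in the other petioles, while the interface libraries against each other ranged from -0.328 to 0.295, and selective stability or movement was not tested.

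PJF15 and PJF23 held more interface-induced miRNA reads per 24-nt siRNA read, 1.32 (counting interval 1.28 to 1.37) and 0.723 (0.711 to 0.736), than any interface library (0.217 to 0.252). Parasite tissue with the make-up of the interface or of shoot tips is argued against by 0.723, the lower of both, since mixing these cannot exceed 0.252. Read transfer in proportion to the pool of the other libraries is argued against, since it would give at most 0.0883, and from interface libraries alone 0.252. Host small RNAs counted at these sequences stay open: the ranks across miRNAs followed those of the interface, with a rho of at least 0.877 in both, but interface tissue holds host cells as well. It also stays open that a part of the interface rich in these miRNAs may have been carried over, or that the miRNAs outlast or outpace siRNAs in host tissue, which was not tested.

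The splits of interface and shoot tip libraries are too few for a share under 0.05. Of 10 splits the real 1 gave 209 parasite features and the highest other 0, and for canonical miRNAs the real split gave 12 and the highest other 1. For canonical miRNAs of interface and proximal petioles the count decides nothing about chance: the real split gave 0, which all 35 of 35 splits match by construction. The highest other split gave 9, which may come from a structure among the libraries other than the groups and was not tested.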
